A study of Mus musculus with 8 samples.

How the data were processed

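RNA-seq libraries were made from epithelial cells of the mouse distal colon, released from the tissue with EDTA and passed through a cell strainer, per the labels' protocols. The 8 libraries fall into 2 groups of 4 by their titles, wild type (WT) and homozygous Degs2 mutant (Degs2_KO), with c57bl6/j as the strain background. The labels do not state that each library came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical.

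Per the submitters' processing notes, the tools were cutadapt 1.9, TopHat2 2.0.10, Cufflinks 2.1.1 and Cuffdiff, with the mm10 build; the order of the steps and the annotation are not given in the sources used here. The deposited table holds estimated counts of fragments per gene and library with a status word for each, per the file headers. The estimated counts deposited by the authors are not whole. Low values within a library are multiples of 1 step, from 0.871 in WT replicate 2 to 1.31 in WT replicate 1, so each library had been scaled by 1 factor. Of values up to 100 fragments, between 96.9% and 97.2% per library came out whole, within 0.02, after division by the step.

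The table lists 54141 Ensembl gene IDs, of which 54074 matched a symbol and 67 did not. Whether the authors' counting used strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart by it. In 47 genes at least 1 library had the status FAIL or HIDATA, which Cuffdiff gives to a failed estimate or a locus with too many fragments. All 119 such values are listed at 0, and those genes were left out of every test except the added fit that kept them at 0. The 612 genes with a LOWDATA status were kept.

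The deposited scaled totals were 43048222, 43399928, 42940037 and 44606092 for WT replicates 1 to 4 and 43973065, 42235113, 41622927 and 42370206 for Degs2_KO replicates 1 to 4. Dividing by the step gave totals, in M fragments, of 32.8, 49.8, 45.3 and 42.4 for WT and 46.2, 43.7, 43.2 and 43.5 for Degs2_KO. At this depth 3 fragments correspond to a scaled count between 2.61 and 3.93, which covers counting error only. The median standard error of a log2 fold change was 0.161, and the 95% interval lay within 2-fold for 81.9% of the tested genes.

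The groups were compared with edgeR 4.0.16 in R 4.3.3. Estimated counts were rounded to whole numbers, genes were filtered with filterByExpr (minimum count 10, minimum total 15), which left 16132 genes, and libraries were normalized with TMM. The test was the 2-sided quasi-likelihood F test with the group as the only term and Benjamini-Hochberg adjustment at 0.05. CPM values are TMM-normalized, and log2 CPM used a prior count of 2. Degs2 also had an exact 2-sided permutation test over 70 assignments.

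Before the data were examined, 35 gene lists were written from general knowledge of the colon epithelium, of sphingolipid metabolism and of other cell types or stress that such a preparation can hold. Of 744 symbols 3 were matched through older symbols and 1 had no match. The 33 lists with at least 3 tested members were tested with limma 3.58.1, by camera with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Counts of members adjusted over the list alone are given beside those over all genes.

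The rule for named genes was also fixed before the data were examined. It takes Degs2, then up to 12 genes per direction past the threshold with groups that do not overlap and a mean log2 CPM of at least 1. With fewer than 5 in a direction, it takes the 5 with the smallest unadjusted p in that direction. From each list it takes members past the threshold or, if none passes, up to 2 with the smallest p. Gene models without a given name, small RNA genes and receptor segments are counted but not named. Some genes that the rule takes from the lists are not reported here. Coordinates are from GENCODE M21 on GRCm38, the assembly called mm10.

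The tests were tried on simulated data with 200 changed genes among 16132, drawn independently from the means and library sizes of these libraries. edgeR called 20.9% of the genes changed 1.5-fold, 61.2% of those changed 2-fold and 81.8% of those changed 4-fold, with 6 false calls among 115. DESeq2 1.42.0 called 40.3%, 74.6% and 84.8%, with 39 false calls among 172. The simulated genes did not vary together as those of the real libraries do, so these rates need not hold for the real comparison.

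The alternatives were median-of-ratios size factors, library totals, DESeq2, limma-trend, limma-voom, no filter, a stricter filter (1 CPM in all 4 libraries of a group and 50 counts in total), a block on the replicate number, a block on adjoining ID numbers (3 pairs), each library left out in turn, stricter thresholds and 1 surrogate variable (sva 3.50.0). Added after the data were seen were a fit without WT replicate 1 and Degs2_KO replicate 3, a fit with the authors' scaling undone, and a fit with failed estimates kept at 0. The median log2 fold change of all genes moved to between -0.012 and 0.004 under these settings, from -0.007. No pair of libraries differed by less than sampling noise (chi-square per degree of freedom at least 17.8), so none was counted as a repeat. The authors' own comparison of the groups was not used here.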

Results

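Gene expression was measured by RNA-seq in epithelial cells of the distal colon from wild-type mice (WT, 4 libraries) and mice homozygous for a mutant allele of Degs2 (Degs2_KO, 4 libraries). Degs2 encodes a sphingolipid desaturase and hydroxylase that makes phytoceramides. The comparison asks how its loss alters the transcriptome of colonic epithelial cells. Scaled totals of estimated counts were between 41622927 and 44606092 per library.

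Degs2 itself was lower in every Degs2_KO library than in every WT library. Its level was 122 ± 20.1 CPM (SD, n = 4) in WT and 58.2 ± 9.08 CPM (SD, n = 4) in Degs2_KO, 47.8% of WT. The WT libraries lay between 106 and 151 CPM and the Degs2_KO libraries between 47.7 and 65.9 CPM. The log2 fold change was -1.07 ± 0.15 (SE), a level 2.09-fold lower (95% interval 1.66 to 2.63). The exact 2-sided permutation test gave p = 0.0286, the smallest that 70 assignments allow. Degs2 had the smallest p of all tested genes, 4.94e-05 by edgeR's quasi-likelihood test. With Benjamini-Hochberg adjustment over all genes edgeR gave 0.796, so it did not pass. DESeq2 called it with an adjusted p of 3.32e-06 and edgeR with 1 surrogate variable at 0.0377, within a range of 3.32e-06 to 1 over 21 settings. Degs2 (ENSMUSG00000021263) lies on the minus strand of chromosome 12 from 108678711 to 108702315 (GRCm38). The end of Evl, annotated from 108554720 to 108688516, overlaps it; Evl was at 1.56 CPM in WT and 2.13 CPM in Degs2_KO. The part of Degs2 that the mutation removes is not given in the sources used here, and counts over exons that remain would still be included.

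**Figure D1:**
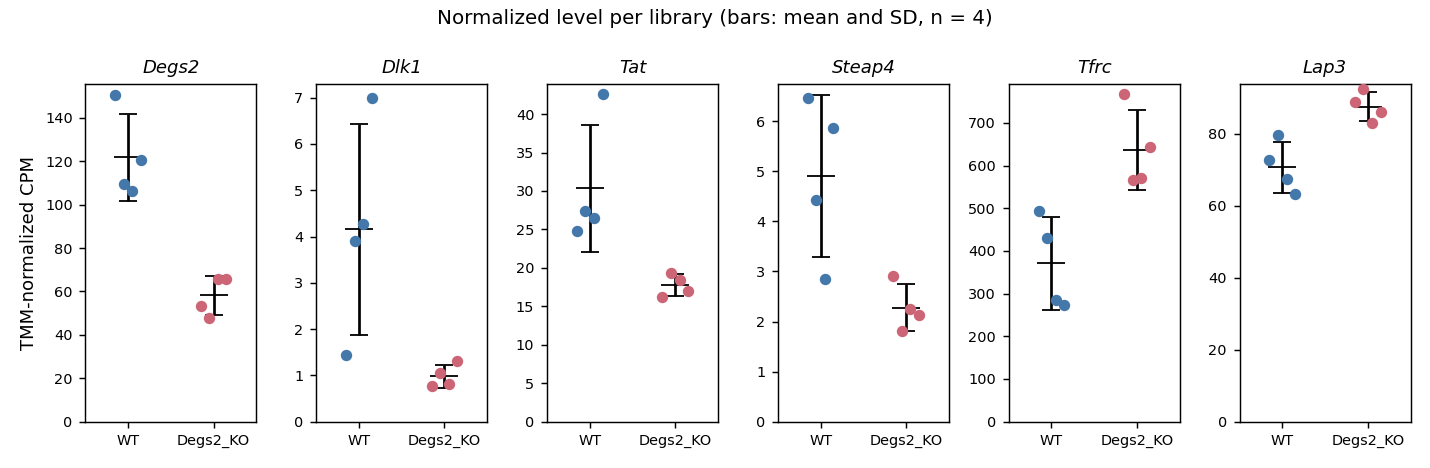
TMM-normalized CPM of Degs2 and 5 of the genes with the smallest unadjusted p, with 1 point per library (WT left, Degs2_KO right) and bars for the mean and SD (n = 4). The Degs2_KO libraries lie between 47.7 and 65.9 CPM for Degs2, under the WT range of 106 to 151 CPM; none of the 6 genes passed edgeR's adjusted threshold.

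No gene passed edgeR's adjusted threshold between the colonic epithelial cells of the genotypes. Of 16132 genes, edgeR's quasi-likelihood test called 0 after Benjamini-Hochberg adjustment, with a smallest adjusted p of 0.796. At an unadjusted p under 0.05 it found 183 genes, 53 higher and 130 lower in Degs2_KO, where evenly spread p-values would give 807. That count was 782 without WT replicate 1, 298 without Degs2_KO replicate 1, 292 without Degs2_KO replicate 3, 434 with 1 surrogate variable, 401 without a filter, 99 with the replicate block and 79 with the ID block. DESeq2 had 39 false calls among 172 in the simulated data, whose genes had passed the count filter. Run on the real data without that filter, it called 2 genes, Degs2 and Dlk1. It had 274 under the unadjusted threshold. limma-trend and limma-voom called 0 each, with 185 and 195 genes under it. The groups did not overlap for 168 genes (1.04%), where chance gives 2.86%. The 95% interval of the fold change lay within 2-fold for 13213 genes and within 1.5-fold for 9738, so larger changes are excluded for most genes but smaller ones are not.

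Among the genes lower in Degs2_KO with the smallest unadjusted p, Dlk1, an imprinted Notch-related ligand, was at 4.15 ± 2.27 CPM in WT and 0.984 ± 0.245 CPM in Degs2_KO (SD, n = 4), a log2 fold change of -2.07 ± 0.43. Dlk1 (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336) starts 751 kb from the end of Degs2. DESeq2 called it with an adjusted p of 0.0133, where the range over 21 settings was 0.0133 to 1. Tat, the tyrosine aminotransferase of tyrosine breakdown, was at 30.3 ± 8.28 CPM in WT and 17.8 ± 1.40 CPM in Degs2_KO. Steap4, a metalloreductase, had a log2 fold change of -1.10 ± 0.27, and Rab6b, a Golgi GTPase, one of -1.42 ± 0.39. None of these passed edgeR's adjusted threshold.

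Of those higher in Degs2_KO, Tfrc, the transferrin receptor that takes up iron, was at 371 ± 109 CPM in WT and 637 ± 93.6 CPM in Degs2_KO (SD, n = 4), a log2 fold change of 0.78 ± 0.21. Pcdh17, a protocadherin, had a log2 fold change of 0.55 ± 0.14. Lap3, a leucine aminopeptidase, had one of 0.31 ± 0.08, Cetn2, a centrin, 0.29 ± 0.09 and Acsl4, a long-chain acyl-CoA synthetase, 0.28 ± 0.09. None of these passed either.

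Tat lies on chromosome 8 from 109990437 to 109999803, Steap4 on chromosome 5 from 7960457 to 7982213 and Rab6b on chromosome 9 from 103111787 to 103185276. Tfrc lies on chromosome 16 from 32608920 to 32632794, Pcdh17 on chromosome 14 from 84443563 to 84539002 and Lap3 on chromosome 5 from 45493374 to 45512691. Cetn2 (72913532 to 72918411) and Acsl4 (142317993 to 142390535) lie on chromosome X.

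The gene lists closest to the function of Degs2 had median log2 fold changes near 0. Of 14 tested genes of de novo ceramide synthesis 9 were higher and 5 lower, with a median log2 fold change of 0.03 and 0 past edgeR's threshold. Degs1, the related ceramide desaturase, had a log2 fold change of 0.31 ± 0.21, and Cers3, a ceramide synthase, -0.60 ± 0.30 at under 1 CPM in both groups. The 30 genes of ceramide turnover and complex sphingolipids split into 15 higher and 15 lower (median -0.001), with Gal3st1 at -0.14 ± 0.09 and Acer2, an alkaline ceramidase, at 0.13 ± 0.08. The 11 genes of phytosphingosine breakdown and alpha oxidation had a median of -0.001, with Acsl5 at 0.10 ± 0.07. limma's camera gave adjusted p-values of 0.769, 0.848 and 0.677 for these lists. The mean and the test differ from the median in sign for phytosphingosine breakdown, and the test differs from both for ceramide turnover.

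Of the 33 lists tested, 9 passed camera with the preset correlation, 8 higher and 1 lower in Degs2_KO, and 0 passed with an estimated correlation or with fry (limma, smallest adjusted p 0.254 and 0.315; mixed fry 0.998). No member of any list passed edgeR's threshold over all genes, and adjusted over the list alone only Dlk1 did, among the neighbours of Degs2.

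Lipid synthesis lists were among the 9. Fatty acid desaturases and elongases were higher for 13 of 15 members, with a median log2 fold change of 0.09 and camera's adjusted p at 1.73e-04 (adjusted p = 0.254 with an estimated correlation). Scd1, the stearoyl-CoA desaturase, had a log2 fold change of 0.44 ± 0.17 and Hsd17b12, a ketoacyl-CoA reductase of elongation, 0.20 ± 0.09. Cholesterol biosynthesis genes were higher for 22 of 25 members, with a median of 0.19 and camera's adjusted p at 6.7e-07 (adjusted p = 0.798 with an estimated correlation). Acat2, an acetyl-CoA acetyltransferase, had a log2 fold change of 0.43 ± 0.17. Fatty acid synthesis had a median of -0.01 over 13 members (Gpam -0.19 ± 0.17, Acaca 0.13 ± 0.14) with camera in the other direction (adjusted p = 0.835). The list of PPAR targets and fatty acid oxidation had a median of 0.02 over 23 members (Slc25a20 -0.21 ± 0.13, Angptl4 0.94 ± 0.91) and an adjusted p of 0.835 by camera; camera called it lower without Degs2_KO replicate 3 (adjusted p 0.0458) and higher without Degs2_KO replicate 4 (adjusted p 0.0435), both with the preset correlation (adjusted p = 0.96 with an estimated correlation and all libraries).

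Lists of secretory and dividing cells also passed camera with the preset correlation. Goblet cell and mucus genes were higher for 17 of 19 members, with a median of 0.18 and an adjusted p of 1.73e-04 (adjusted p = 0.298 with an estimated correlation). Examples were Zg16, a mucus lectin, at 0.27 ± 0.18 and Capn9 at 0.28 ± 0.15. Muc2 went the other way, at -0.43 ± 0.85, and Clca1 and Fcgbp were not tested because estimates had failed. Genes of the unfolded protein response were higher for 22 of 25 members, with a median of 0.19 and camera's adjusted p at 4.07e-07 (adjusted p = 0.798 with an estimated correlation). The endoplasmic reticulum chaperone genes Canx and Dnajb11 had log2 fold changes of 0.17 ± 0.08 and 0.23 ± 0.13. Proliferation genes were higher for 30 of 32 members, with a median of 0.11 and camera's adjusted p at 4.03e-07 (adjusted p = 0.798 with an estimated correlation). Pcna, the DNA clamp of replication, had a log2 fold change of 0.31 ± 0.13 and Mcm2, a replicative helicase subunit, 0.36 ± 0.17. Without WT replicate 4, where this list was lowest, the proliferation median was -0.03 and camera's adjusted p 0.261. Tuft cell genes were higher for 16 of 17 members, with a median of 0.23 and camera's adjusted p at 1.73e-04 (adjusted p = 0.798 with an estimated correlation), and Rgs13 at 0.46 ± 0.30. WT replicate 1 and Degs2_KO replicate 3 had the highest tuft cell medians, 0.72 and 0.76, and without Degs2_KO replicate 3 the median log2 fold change was -0.024 and camera's adjusted p 0.289.

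MHC and interferon-gamma response genes were higher for 27 of 28 members, with a median log2 fold change of 0.33 and camera's adjusted p at 1.86e-08 (adjusted p = 0.798 with an estimated correlation). The MHC class II genes H2-Eb1 and H2-DMb1 had log2 fold changes of 1.5 ± 0.58 and 1.11 ± 0.44. H2-Eb1 was at 4.89 ± 2.82 CPM in WT and 13.9 ± 8.24 CPM in Degs2_KO (SD, n = 4), and Degs2_KO replicate 4 lay within the WT range at 3.18 CPM. The list was lowest in WT replicate 3 at -0.98, as were the interferon-stimulated list at -1.10 and the T cell list at -1.25. The interferon-stimulated list had a median of -0.03 over 28 members with camera in the other direction (adjusted p = 0.212), and Bst2 at 0.30 ± 0.26. The direction that camera gave the interferon-stimulated and T cell lists differed with the library left out. Without WT replicate 3 camera called both lower in Degs2_KO, each with an adjusted p of 0.00178. It called the interferon-stimulated list higher without WT replicate 1, WT replicate 4 or Degs2_KO replicate 4 (adjusted p 0.0193, 2.69e-07 and 0.000846) and the T cell list likewise (adjusted p 0.00146, 0.0336 and 0.0202). These calls use the preset correlation; with all libraries and an estimated correlation, camera gave both lists an adjusted p of 0.926. The 20 genes of NF-kappaB and inflammatory cytokines had a median of -0.04 (camera adjusted p = 0.528), with Tnf at -0.50 ± 0.33 and Relb at -0.18 ± 0.13. Antimicrobial and epithelial defence genes were lower for 14 of 19 members, with a median of -0.32 and an adjusted p of 0.0756 by camera. Saa1, an acute phase protein made by the epithelium, was at 503 ± 210 CPM in WT and 261 ± 68.8 CPM in Degs2_KO, and Saa2 had a log2 fold change of -0.99 ± 0.32. Camera called this list lower without WT replicate 3 or Degs2_KO replicate 4 (adjusted p 0.00178 and 0.0403), with the preset correlation (adjusted p = 0.798 with an estimated correlation and all libraries).

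Other epithelial lists did not pass with all 8 libraries. The median log2 fold change was -0.09 for absorptive colonocyte genes (8 higher, 18 lower; Slc20a1 -0.54 ± 0.30, Mep1a -0.30 ± 0.23) and 0.04 for stem cell genes (14 higher, 6 lower; Ephb2 0.10 ± 0.08, Cdca7 0.22 ± 0.18), each with an adjusted p of 0.441 by camera. It was -0.14 for enteroendocrine genes (3 higher, 16 lower; Pax4 and Cpe at -0.68 ± 0.49 and -0.37 ± 0.28; camera adjusted p = 0.185). Tight and adherens junction genes had a median of -0.03 (camera adjusted p = 0.769), with Ocln at -0.12 ± 0.11 and Cldn15 at 0.24 ± 0.30. Xenobiotic and retinoid metabolism had a median of -0.11 (adjusted p = 0.19 by camera; Cyp3a13 -0.25 ± 0.18, Cyp2s1 -0.24 ± 0.18). Oxidative phosphorylation had a median of 0.03 (adjusted p = 0.104 by camera; Sdhd 0.08 ± 0.08, Ppargc1a -0.31 ± 0.24). For p53 and apoptosis the median was 0.009 and the mean -0.005 (camera adjusted p = 0.835), with Bcl2l11 at -0.28 ± 0.12 and Pmaip1 at -0.43 ± 0.22. Circadian clock genes had a median of -0.04 and a mean of 0.003 (camera adjusted p = 0.463), with Per3 at -0.36 ± 0.27 and Cry1 at 0.16 ± 0.21. With 1 library left out, camera called enteroendocrine genes lower without WT replicate 4 or Degs2_KO replicate 3 (adjusted p 0.00112 and 3.61e-05). It called xenobiotic and retinoid metabolism lower without WT replicate 2 or Degs2_KO replicate 3 (adjusted p 0.00425 and 0.000119) and circadian clock genes lower without Degs2_KO replicate 3 (adjusted p 0.0175). It called oxidative phosphorylation higher without WT replicate 1, WT replicate 4, Degs2_KO replicate 2 or Degs2_KO replicate 4 (adjusted p 0.00441, 0.0182, 0.00283 and 0.0173). Stem cell genes were called higher by camera without Degs2_KO replicate 1 (adjusted p 0.042). All of these calls use the preset correlation; with all libraries and an estimated correlation, camera gave each of these 5 lists an adjusted p of 0.926.

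Markers of other cells, of handling and of position along the gut varied widely between libraries. Fibroblast genes were lower for 10 of 11 members, with a median log2 fold change of -0.74 and camera's adjusted p at 0.0112 (adjusted p = 0.798 with an estimated correlation). WT replicate 4 held the highest fibroblast level, 2.1 on the log2 scale above the mean of all libraries, and without it the median log2 fold change was 0.049 and camera's adjusted p 0.627. It was also above 0.05 without Degs2_KO replicate 3 (0.0826) and without Degs2_KO replicate 4 (0.153). The call was also lost with the stricter filter (median -0.178, camera adjusted p 0.421) and without both WT replicate 1 and Degs2_KO replicate 3 (median -0.787, camera adjusted p 0.0508). Dcn, a matrix proteoglycan gene, was at 15.3 CPM in WT replicate 4 and between 0.427 and 6.43 CPM in the other libraries. The list of dissociation and heat shock stress was higher for 20 of 21 members, with a median of 0.30 and camera's adjusted p at 0.00275 (adjusted p = 0.906 with an estimated correlation); Hspa1a had a log2 fold change of 0.85 ± 0.58 and Dnajb1 0.27 ± 0.20. This list was lowest in WT replicate 1 (-0.83) and Degs2_KO replicate 3 (-0.52). Without WT replicate 1 its median log2 fold change was 0.061 and camera's adjusted p 0.917. These values were 0.205 and 0.163 without Degs2_KO replicate 1, and 0.164 and 0.104 without Degs2_KO replicate 2.

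The remaining lists of other cells had medians of 0.006 for T cell (mean -0.08), -0.20 for myeloid, -0.07 for smooth muscle, -0.05 for endothelial and -0.28 for enteric neuron and glia genes, with camera's adjusted p between 0.19 and 0.835; without WT replicate 3 camera called the myeloid list lower (adjusted p 0.0306; with all libraries, adjusted p = 0.926 with an estimated correlation). Examples were Cd8b1 at -0.66 ± 0.57, C1qa at -1.5 ± 0.72, Csrp1 at 0.19 ± 0.15, Pecam1 at -0.60 ± 0.28 and Snap25 at -0.56 ± 0.37. Derl3 was the only tested member of the B cell list, at 0.28 ± 0.37. Xist, the only tested sex-linked gene, was at 470 CPM or more in each of the 8 libraries. The 10 tested neighbours of Degs2 had a median of -0.006 and an adjusted p of 0.677 by camera, with Wars at 0.23 ± 0.12.

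The libraries did not separate by genotype. The first principal component held 50.3% of the variance and set WT replicate 1 (-53.9) and Degs2_KO replicate 3 (-59.1) apart from the other libraries, which lay between -1.1 and 43. These 2 libraries had the lowest medians of the colon position list (-0.58 and -0.49) and the highest of the small intestine and proximal gut list (0.67 and 0.92). Hoxd13, which marks the hindgut end of the body axis, was at 0.699 CPM in WT replicate 1 and 0.312 CPM in Degs2_KO replicate 3 and between 38.8 and 85.3 CPM elsewhere. Between the genotypes, the position list had a median log2 fold change of -0.18 (adjusted p = 0.975 by camera; Hoxd9 and Hoxd10 at -0.90 ± 0.93 and -0.77 ± 1.21). The small intestine and proximal gut list had one of -0.31 (adjusted p = 0.0829 by camera; Rbp2 -0.31 ± 0.17, Anpep -0.36 ± 0.27). Camera called the latter list lower in 7 of 21 settings, with an adjusted p down to 0.000244 (1 surrogate variable). Among them were the fits without WT replicate 2, WT replicate 3 or Degs2_KO replicate 3 (adjusted p 0.0183, 0.0397 and 0.0016). These calls use the preset correlation; with all libraries, camera gave this list an adjusted p of 0.798 with an estimated correlation and fry one of 0.982. Without these 2 libraries, a fit chosen after the data were seen, edgeR again called 0 genes, with 650 at an unadjusted p under 0.05.

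**Figure D2:**
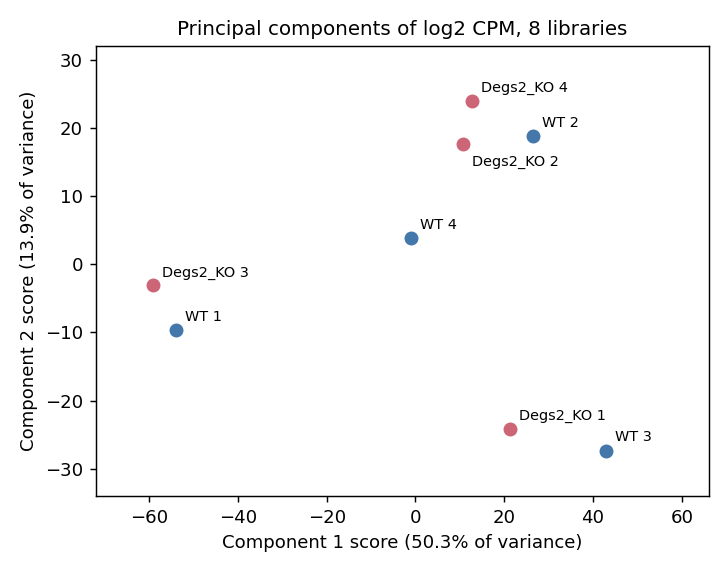
Scores of the 8 libraries on the first (horizontal, 50.3% of variance) and second (vertical, 13.9%) principal components of log2 CPM, without units; WT libraries are blue and Degs2_KO libraries red. WT replicate 1 and Degs2_KO replicate 3 sit at -53.9 and -59.1 on the first component, and the others between -1.1 and 43.

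**Figure D3:**
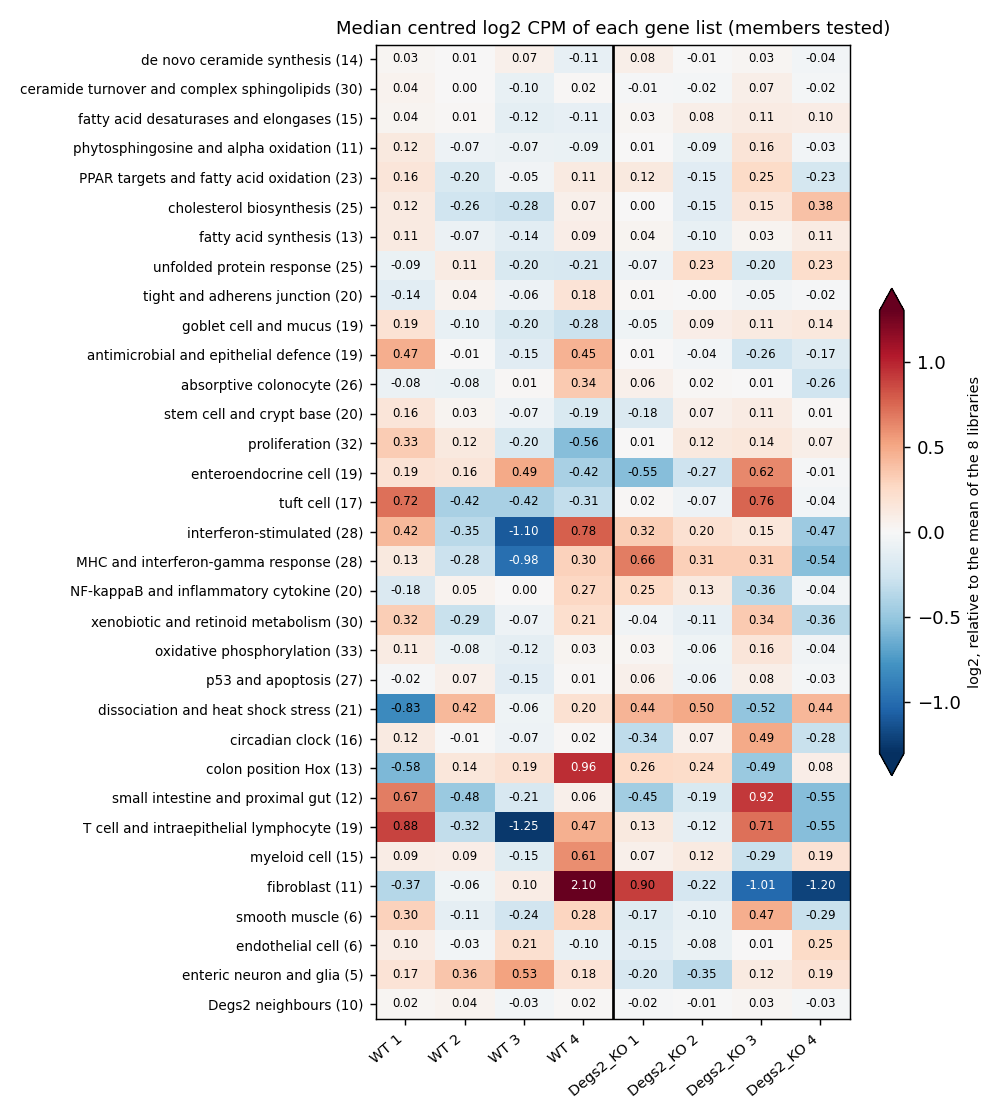
Median over members of each gene list (tested members in parentheses) of log2 CPM centred on the mean of the 8 libraries, with 1 column per library, WT left of the line and Degs2_KO right. The fibroblast list reaches 2.1 in WT replicate 4, and the tuft cell list 0.72 and 0.76 in WT replicate 1 and Degs2_KO replicate 3.

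Some abundant mucus and epithelial genes could not be compared because an estimate had failed in at least 1 library. Clca1, a goblet cell secretory protein, was listed at 0 with a HIDATA status in Degs2_KO replicates 1, 2 and 4. Its estimated counts were 557718 to 996883 in the WT libraries and 692821 in Degs2_KO replicate 3. Fcgbp, another mucus protein, was listed at 0 with that status in Degs2_KO replicates 2 and 4, and at 393611 to 771908 elsewhere. Hnf4a, an epithelial transcription factor, was listed at 0 with a FAIL status in WT replicates 3 and 4 and lay between 40550 and 49823 in the other libraries.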

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

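The tests of position along the colon and of the failed estimates were chosen only after the result they measure had been seen. So were those of goblet cell loss and of how many lists other groupings call. Outcomes were written down beforehand for the count of genes called, gene length and GC, the region around Degs2, and fibroblasts for Dlk1. None was written for the splits by where WT replicate 1 and Degs2_KO replicate 3 fall. The same holds for the covariate fits of Meg3 and Rian and the check for single outlying libraries. The 8 libraries can be split 4 and 4 in 35 ways. For the count of 0 genes called by edgeR (183 at an unadjusted p under 0.05; DESeq2 called 2, limma-trend and limma-voom 0), the comparison says nothing about chance: a count of 0 is matched by all 35 splits whatever the data, and the highest other split gave 1. For the 9 gene lists called by camera with the preset correlation, 23 of the 35 splits gave as many and the highest other gave 16, so chance cannot be excluded for that count. The 15 splits that put WT replicate 1 and Degs2_KO replicate 3 in the same group had a median of 1608 genes at an unadjusted p under 0.05 (513 to 3000), and the 20 that part them a median of 273 (107 to 863). The ranges overlap. The pair was chosen because it stood apart in these same data, so higher counts with the pair together are no separate evidence.

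WT replicate 1 and Degs2_KO replicate 3 stood apart together, with a correlation of 0.75 between their deviations from the group means across genes, which are not independent replicates. A bias on gene length or GC content is argued against: with smooth trends on exon length and GC taken out of every library, the correlation was 0.749. Tissue from further up the colon is a candidate explanation that stays open: for 8 of 13 position genes these were the 2 lowest of the 8 libraries (61.5%, against 16.6% of all tested genes), among them Hoxd10, Hoxd11, Hoxd12, Hoxd13, Hoxa13 and Hoxb13. Hoxb6, Hoxb7, Hoxb8 and Hoxb9, which are expressed further forward along the body axis, were instead highest in both (Hoxb6 at 46.5 and 44.5 CPM, elsewhere between 1.02 and 8.92 CPM). Each genotype holds 1 of these libraries. Beyond gene length, GC content and position, no explanation for this pair was tested.

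Dlk1, called by DESeq2 and not by edgeR, was lower in each Degs2_KO library (0.771 to 1.31 CPM) than in each WT library (1.45 to 6.99 CPM). In the simulated data, with filtered genes drawn independently, 39 of DESeq2's 172 calls were false. The real DESeq2 fit had no count filter, so that rate does not give the chance that this call is false. A change of the whole region around Degs2 is argued against: the other 15 tested genes within 1 Mb had a median log2 fold change of -0.062, with quartiles at -0.18 and 0.015. The tested genes closest to Dlk1 had the lowest values of these, between -0.96 and -0.76. They were Meg3, Rian and a gene model without a given name. A change limited to Dlk1 and these neighbours was not tested. The imprinted transcripts Meg3 and Rian next to Dlk1 did not pass, and a covariate for the fibroblast list took them from -0.96 ± 0.46 to -0.51 ± 0.55 and from -0.76 ± 0.44 to -0.51 ± 0.56, with Meg3 highest (134 CPM) in WT replicate 4, where fibroblast genes were highest. The same covariate took Dlk1 from -2.07 ± 0.43 to -1.79 ± 0.50, and its unadjusted edgeR p from 0.00104 to 0.00785. This met neither the outcome written beforehand for fewer fibroblasts nor the one against it. Fewer fibroblasts therefore cannot be told apart from genotype as a part of the cause. Dlk1 was highest in WT replicate 4 (6.99 CPM; fibroblast median 2.1) but lowest in Degs2_KO replicate 1 (0.771 CPM), where the fibroblast median was 0.897. None of the 11 tested fibroblast genes is in another list, and the most abundant in WT were Pdgfrb (8.89 CPM in WT, 8.17 CPM in Degs2_KO), Dcn (6.36 and 2.55 CPM) and Vim (5.03 and 4.34 CPM); direct effects of Degs2 were not tested.

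Clca1 and Fcgbp were listed at 0 in some Degs2_KO libraries, and Muc2 was at 522 CPM in Degs2_KO replicate 3 against 5907 to 24564 CPM elsewhere. Each zero of Clca1 and Fcgbp carries a HIDATA status, and all 119 values with a FAIL or HIDATA status are 0. These zeros are therefore not measured levels, and whether either gene changed cannot be told from them. Loss of goblet cells is argued against: in the 4 libraries concerned the lowest median of the other 18 goblet genes was -0.024. The low Muc2 value carries an OK status, so the zeros of the other genes do not account for it, and its source stays open. With the zeros kept, Clca1 had a log2 fold change of -2.20, which rests on those zeros, and an edgeR adjusted p of 1.

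Of 224 groups of 4 values checked for 1 library far from the other 3, 16 had one. Independent, normally distributed values would give about 1 in 20, or 11.2. The checked values are not independent, since lists were checked beside their own members, so 16 cannot be set against chance. In WT replicate 1, Capn9 was at 86.3 CPM (others up to 64.8), Rgs13 at 7.23 CPM (others up to 3.99), Sdhd at 232 CPM (others up to 214.5) and C1qa at 2.51 CPM (others up to 0.406). The medians of its tuft cell list and its phytosphingosine and alpha oxidation list were 0.72 and 0.12, with the other WT libraries up to -0.31 and -0.07. In WT replicate 4, Tat was at 42.6 CPM (others up to 27.4) and Col6a2 at 2.58 CPM (others up to 0.602). Xist was at 1515 CPM in WT replicate 3 (others up to 663) and at 1296 CPM in Degs2_KO replicate 1 (others up to 602). Degs2_KO replicate 1 also had Cpe at 3.42 CPM (others from 5.92) and an unscaled total of 46.2 M fragments (others up to 43.7). In Degs2_KO replicate 3 the list medians were 0.76 for tuft cells (others up to 0.02), -0.52 for dissociation and heat shock stress (others from 0.44) and 0.074 for ceramide turnover and complex sphingolipids (others up to -0.015). Rbp2 was at 5.50 CPM in Degs2_KO replicate 4 (others from 8.44).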

How the results depend on the processing

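The fits without WT replicate 1 and Degs2_KO replicate 3, with the authors' scaling undone and with failed estimates kept at 0 were chosen after seeing the data. edgeR called 0 genes (183 at an unadjusted p under 0.05), as did limma-trend and limma-voom, while DESeq2 called 2 and edgeR with 1 surrogate variable 1; the cause was not tested. Leaving out each library gave 0 throughout, with 782 genes at an unadjusted p under 0.05 without WT replicate 1, 298 without Degs2_KO replicate 1 and 292 without Degs2_KO replicate 3. That count was 650 without both WT replicate 1 and Degs2_KO replicate 3, 434 with the surrogate variable, 401 without a filter, 99 with the replicate block and 79 with the ID block. Degs2 had log2 fold changes of -1.06 with DESeq2 (adjusted p 3.32e-06) and -1.08 with the surrogate variable (adjusted p 0.0377), and from -1.13 to -0.94 with a library left out. Camera's 9 lists became 0 with an estimated correlation and 0 with fry, which allow for genes of a list varying together, and ranged from 9 to 14 with a library left out, highest without WT replicate 3. Of 692 list results, 620 stayed on the same side of the threshold, 31 lost a call and 38 gained one. The direction differed from the main fit in 55 of the 692, mostly without a call in either fit, and the cause was not tested. In 3 of the 55, camera's direction turned from an uncalled to a called result the other way. These were PPAR targets without Degs2_KO replicate 3 (median log2 fold change -0.109, range with a library left out -0.109 to 0.074) and, without WT replicate 3, interferon-stimulated (-0.24, range -0.24 to 0.252, -0.025 with all libraries) and T cell genes (-0.293, range -0.371 to 0.398). Gained calls were most frequent for the small intestine and proximal gut list (7 of 21 settings) and oxidative phosphorylation (5), with 4 each for the antimicrobial, enteroendocrine, xenobiotic, interferon-stimulated and T cell lists. The fibroblast list lost its call in 8 settings. Of 1557 named-gene results besides Degs2, 1556 stayed uncalled, 1 gained a call (Dlk1 with DESeq2) and 11 changed sign without a call. The first component held 64% of the variance with the 500 most variable genes. The labels do not state that the replicate numbers pair the libraries. Deviations of same-numbered libraries correlated at -0.42, 0.44, -0.56 and -0.10 for replicates 1 to 4. Numbers 1 and 3 each include 1 library of the pair that stood apart, so these values cannot exclude a pairing. WT replicate 2 and Degs2_KO replicate 2 had the lowest chi-square per degree of freedom, 17.8. With the replicate block edgeR called 0 genes, Degs2 had a log2 fold change of -1.07 (adjusted p 1) and camera called 10 lists. The block on adjoining ID numbers, which uses only 6 libraries, gave 0 genes, -0.975 for Degs2 (adjusted p 1) and 11 lists; it ended camera's calls of the unfolded protein response (median 0.084, adjusted p 0.17), proliferation (-0.017, 0.792) and fibroblast lists (-0.214, 0.792). For lists, limma-trend uses the same log2 CPM as camera and gives no separate result. At this depth and spread, the 95% interval lay within 1.5-fold for 60.4% of genes.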

Other observations

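The genes below were chosen after the data were seen, from the 12 with the largest loading in each direction on the first principal component. Of the lists fixed beforehand that hold some of them, the absorptive colonocyte list (Car1, Slc51a, Atp12a) had medians of -0.08 in WT replicate 1 and 0.005 in Degs2_KO replicate 3. The xenobiotic and retinoid list (Aldh1a1) was highest in these libraries, at 0.319 and 0.344, as was the small intestine and proximal gut list (Slc10a2), at 0.67 and 0.92. Its member Slc37a2 went the other way, at 85.8 and 32.1 CPM against 208.5 to 554.5 CPM. The dissociation and heat shock list (Fosb, Klf2) was lowest in them, at -0.83 and -0.52. Car1, a carbonic anhydrase of colonocytes, was at 6179 and 6570 CPM in these libraries and between 522 and 1941 CPM in the others. Slc10a2, the bile acid transporter of the ileum, was at 101 and 70.3 CPM against 2.11 to 11.7 CPM. Slc51a, a subunit of the transporter that exports bile acids, was at 59.7 and 57.7 CPM against 5.50 to 12.7 CPM. Aldh1a1, a retinal dehydrogenase, was at 278 and 246 CPM against 17.4 to 73.4 CPM, and Isx, an intestinal homeobox gene that responds to retinoic acid, at 63.3 and 87.7 CPM against 5.26 to 38.9 CPM. Among genes low in both, Atp12a, a proton pump subunit, was at 84.7 and 63.8 CPM against 299 to 591 CPM. Fosb, an immediate early gene, was at 26.7 and 16.6 CPM against 283 to 492 CPM. Klf2 was at 3.16 and 2.23 CPM against 25.9 to 45.3 CPM, and Tgm3, a transglutaminase, at 292 and 279.5 CPM against 1038 to 2404 CPM.

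WT replicate 3 and Degs2_KO replicate 1 also shared features that do not follow genotype. Their log2 CPM deviations had Spearman correlations with GC content across genes of -0.289 and -0.287, where the other libraries lay between 0.014 and 0.172. Lcor was at 68.3 and 61.8 CPM in these libraries and between 3.12 and 4.87 CPM in the others. Zfp871 was at 61.1 and 54.2 CPM against 3.12 to 5.67 CPM. The correlation between the deviations of these libraries across genes was 0.512, and 0.475 with smooth trends on exon length and GC taken out.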
